A study of Mus musculus with 4 samples.

How the data were processed

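The data are RNA sequencing of 4 mouse leukaemia cell lines with 1 library each: the sensitive parental lines B117P and B140P and the highly Ara-C resistant lines B117H and B140H made from them. The authors deposited FPKM values per gene with mm9 coordinates and no counts, confidence intervals or p-values. Per the submitters' processing notes, TopHat2 2.0.4 and Cuffdiff were used with the mm9 build. The FPKM values were taken as deposited and no reads were realigned. Listed starts were counted from 0, as 6285 of the 19357 symbols found in a RefSeq table had equal spans on that reading against 434 on the other, so 1 was added to each start. Transcript length and GC content came from the GENCODE M21 annotation of GRCm38, for 99.0% of expressed genes.

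Genes with a mean FPKM of 1 or more over the 4 libraries, 10066 of 21889, were compared as log2 ratios of FPKM with a pseudocount of 1. A gene was called changed when its ratio was at least 2-fold. With 1 library per line there is no test within a lineage. The same rule was applied between the parental lines and between the resistant lines. Genes changed in both lineages were counted beside the number that independent lists of the same sizes would share. For the paired comparison of resistant with sensitive lines, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with the lineage as a block, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. That fit had 1 residual degree of freedom. The resistant lines pair with the parental lines as the series labels state.

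The median log2 ratio of each of 34 planned gene lists was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists at or below percentile 2.5 or at or above 97.5 are said to stand apart, which describes these libraries and is not a p-value. The sex-linked list had 2 expressed genes and was not placed, which left 33. Medians of chromosomes and of windows of 25 neighbouring expressed genes were compared with 10000 random draws of as many genes, and overlapping windows outside all draws were merged into regions. Windows overlap, so their count is not a count of independent events.

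The genes named were set by a rule fixed with those lists. It takes, in each lineage, the 10 largest rises and 10 largest falls, up to 10 genes changed the same way per direction, the 5 each way with opposite changes, every Ara-C gene past the 2-fold rule with Dck always first, and up to 4 members of each other list with the largest ratios. Small RNA genes and unnamed clones are counted and not named among the largest changes. Other genes are said to be chosen after their values were seen.

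Depth was estimated from the spacing of low FPKM values times transcript length in 840 single-transcript genes of at least 3 kb. Between 63 and 89 low values per library were tested, and a value counted as whole within 0.15 fragments. The share of the parental FPKM left was given an exact Clopper-Pearson 95% interval from the fragments estimated in this way, which covers counting error only. Whole counts were not recovered for all genes, so no count-based test was run.

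The steps were tested on simulated data with 10066 genes, 200 of them changed, and noise with an SD of 0.15 on the log2 scale. In the simulated lineage B117, the 2-fold rule found 37.5% of genes changed exactly 2-fold, 100% of those changed 4-fold and 100% of those changed 8-fold, with 0.0% of unchanged genes past it. In the simulated lineage B140 it found 32.8% of the 2-fold changes and 100% of the 4-fold and 8-fold ones. A list of 20 genes raised by 0.5 came out at percentile 100, and 2.5% and 2.0% of unchanged lists fell outside the central range in the lineages. A raised chromosome 12 was recovered in full, with 1 and 0 regions found elsewhere. The limma fit called 98.4% of 2-fold and 100% of larger changes, and 20 of 9507 unchanged genes. Both simulated lineages were given the same changes, while the real log2 ratios of the lineages had a Pearson correlation of -0.10. The rates hold for the simulated setting and cannot be read as rates for the real libraries.

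The alternatives tried were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, a 4-fold rule, libraries centred on the median ratio, TPM, windows of 15 and 50 genes, and for limma no block, no trend, quantile normalization and leaving out each library without the block. Leaving out small RNA genes, leaving out genes listed at 0, TPM without small RNA genes and subtraction of the median of 25 neighbouring genes were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.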

Results

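RNA was sequenced from 4 mouse acute myeloid leukaemia cell lines of the BXH-2 strain, an inbred strain in which an endogenous retrovirus causes myeloid leukaemia. B117P and B140P are parental lines sensitive to cytarabine (Ara-C), a deoxycytidine analogue that blocks DNA synthesis after it is phosphorylated in the cell. B117H is a highly resistant line made from B117P, and B140H one made from B140P. Each parental line and its resistant derivative are called a lineage here, B117 and B140. The labels give an Ara-C IC50 of about 150 ng/ml for B117P and 160 µg/ml for B117H, a ratio of 1067. For B140P and B140H they give about 110 ng/ml and 60 µg/ml, a ratio of 546. The cells were passaged without Ara-C. There was 1 library per line, so no value below has a replicate error within a line, and a change within a lineage is described by its size alone.

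The deposited values were FPKM for 21889 genes, and 10066 genes with a mean FPKM of 1 or more over the 4 libraries entered the comparisons as expressed genes. Read counts were not used here. The spacing of low values in 840 genes with a single transcript of at least 3 kb gave an estimated 22190000 fragments for B117P, 19730000 for B117H, 19110000 for B140P and 24730000 for B140H. Of the low values, 78.7%, 75%, 77.3% and 85.7% in those libraries lay within 0.15 of a whole number of fragments. The 30% that would do so by chance holds for a unit set without these values. Here the unit of 1 fragment came from the peak of the same values, so those in the peak count as whole by construction. The shares are therefore no independent check of the depth. At these depths 3 fragments on a 2 kb transcript correspond to between 0.0607 and 0.0785 FPKM. The libraries of a lineage were alike, with a Pearson correlation of log2(FPKM + 1) across genes of 0.91 between B117P and B117H and 0.94 between B140P and B140H. No correlation across the lineages was above 0.84. The listed coordinates of 6 multi-copy genes differed between the lineages and none within a lineage, so the lineages may have been normalised separately, and levels set side by side across lineages below carry that limit. Small RNA genes took most of the FPKM total of B117P, with Mir24-1 listed at 13900000 FPKM. Scaling to TPM over all genes, one of the alternatives tried, therefore made a pseudocount of 1 equal to 24.03 FPKM in B117P and 1.44 FPKM in B117H, and its outcome is given with the other alternatives only.

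The first question is which genes of Ara-C uptake and metabolism differed between each resistant line and its parent. Dck, which encodes deoxycytidine kinase, the enzyme of the first phosphorylation of Ara-C, fell in both resistant lines. Its FPKM went from 20.1 in B117P to 3.31 in B117H and from 17.8 in B140P to 2.44 in B140H. These are log2 ratios of -2.29 and -2.45, with a mean of -2.37 and an SD of 0.11 over the 2 lineages. B117H kept 16.5% of the parental FPKM, with a 95% counting interval of 14.1% to 19.1%. B140H kept 13.8%, with an interval of 11.7% to 16.1%. These intervals are exact Clopper-Pearson intervals on the estimated fragments and cover counting error only. Dck lies on chromosome 5 from 89194038 to 89212302 in the mm9 build.

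Among the 32 expressed genes of the Ara-C list, fixed before the data were examined, Dck alone passed the 2-fold rule in both lineages. In lineage B117, 1 gene rose, 2 fell and 29 did not pass the rule. Nt5e, a cell-surface nucleotidase that dephosphorylates nucleoside monophosphates outside the cell, fell from 26.4 to 9.58 FPKM. Nt5c3l, a cytosolic nucleotidase, rose from 4.42 to 13.2 FPKM, but its listed span overlaps Fkbp10. In lineage B140, 1 gene rose, 1 fell and 30 did not pass. Dguok, the mitochondrial deoxyguanosine kinase, rose from 7.10 to 15.7 FPKM. Slc29a1, the equilibrative transporter that carries Ara-C into the cell, was at 50.3 and 50.1 FPKM in lineage B117 and at 64.9 and 98.5 FPKM in lineage B140. Samhd1, which hydrolyses Ara-CTP, was at 21.3 and 24.2 FPKM in lineage B117 and at 27.1 and 29.7 FPKM in lineage B140. Rrm2, a subunit of ribonucleotide reductase, was at 83.4 and 111 FPKM in lineage B117 and at 113 and 174 FPKM in lineage B140. Slc29a1, Samhd1 and Rrm2 were chosen after their values were seen. The list as a whole had a median log2 ratio of 0.01 in lineage B117 and 0.19 in lineage B140, at percentiles 73.4 and 72.3 of expression-matched random lists.

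The expressed neighbours of Dck were less reduced than Dck itself or not reduced at all. The 10 expressed genes on each side of it span 15.1 Mb. Their median log2 ratio was -0.54 in lineage B117 and 0.04 in lineage B140. In lineage B117 this median was below all 10000 random lists, and 3 of the 20 neighbours fell, the lowest being Afp, the alpha-fetoprotein gene, at -1.25. In lineage B140 the lowest neighbour, Stap1, was at -0.56 and none passed the rule. The nearest neighbours, Mobkl1a and Cox18, were at -0.14 and -1.05 in lineage B117 and at -0.01 and 0.18 in lineage B140.

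**Figure D1:**
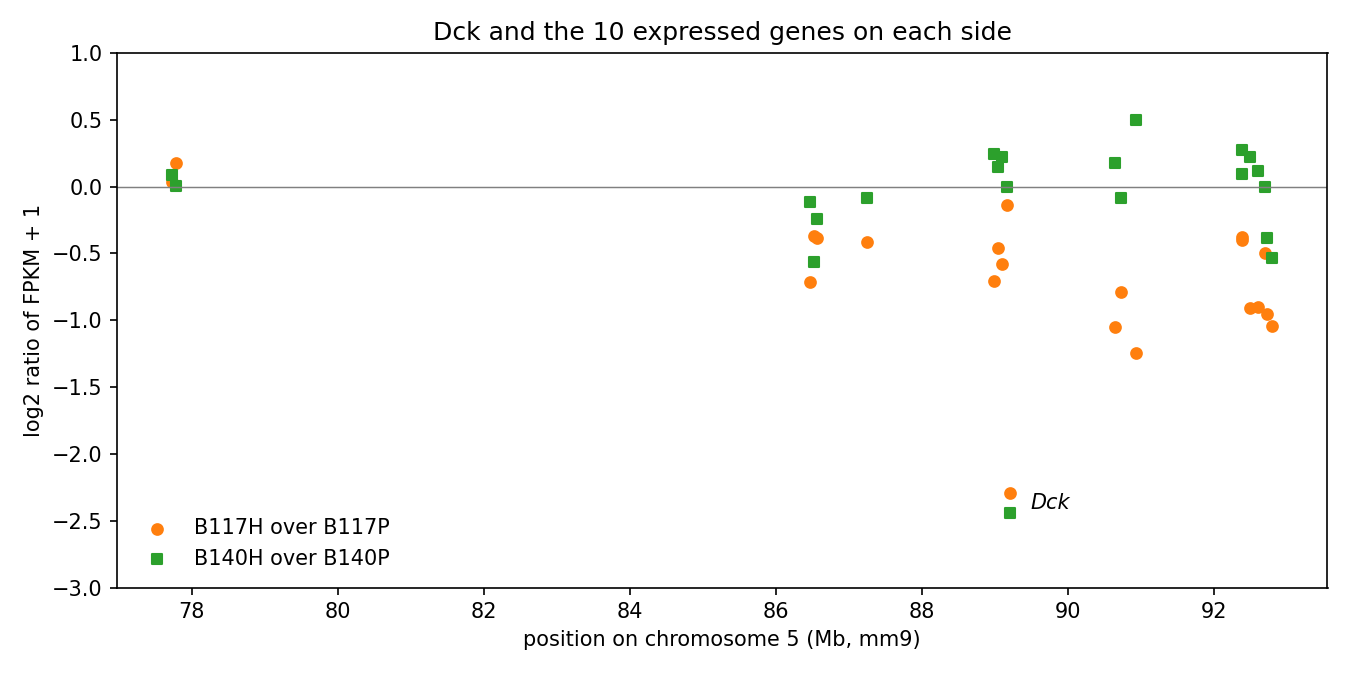
Log2 ratio of FPKM + 1, resistant over parental line, of Dck and the 10 expressed genes on each side of it on chromosome 5 (position in Mb, mm9), for lineage B117 and lineage B140. Dck lies at -2.29 and -2.45, below each of its neighbours, whose median is -0.54 in lineage B117 and 0.04 in lineage B140.

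Taking both lineages as a pair of replicates of the change with resistance, limma with the lineage as a block gave a mean log2 ratio for Dck of -2.37 with a standard error of 0.23, lower in 2 of 2 lineages. Its adjusted p was 0.13 over all 10066 expressed genes and 0.00206 when adjusted over the list alone, the only gene of the 32 called that way. This rests on 1 residual degree of freedom and on variance borrowed from other genes. Without the filter on low values the adjusted p over the list alone was 0.191, and without the block it was between 0.0917 and 0.249 when any of the 4 libraries was left out. Over all genes limma called 0 genes at an adjusted p of 0.05, and 218 had an unadjusted p under 0.05. With a minimum mean FPKM of 5 it called 4, all small RNA genes. Without the block it called 0, but 3 when B117H was left out and 10 when B140P was left out.

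Among the genes other than small RNA genes with the lowest limma p-values, Dck was followed by Ifitm1 and Mpo, both lower in 2 of 2 resistant lines and neither called over all genes. Ifitm1, an interferon-inducible membrane protein, had a log2 ratio of -2.33 with an adjusted p of 0.541. Mpo, the myeloperoxidase of neutrophil granules, had one of -2.10 with the same adjusted p. Adjusted over the list alone, Mpo was called among 17 neutrophil and granulocyte genes (adjusted p = 0.0101), and H2-Ob, a chain of the peptide-loading regulator H2-O, among 7 MHC class II genes (adjusted p = 0.0356). H2-Ob had log2 ratios of 1.22 and 0.87. None of the other 31 lists had a gene called over the list alone. Each list, the Ara-C list included, was adjusted by itself and not across lists, so some calls of this kind could arise by chance. The calls of Mpo and H2-Ob also rest on 1 residual degree of freedom.

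In B117H, granulocyte and monocyte genes were lower than in B117P, and Itgax and Vpreb1 were among the largest rises. Ms4a3, a marker of granulocyte and monocyte progenitors, fell from 218 to 15.3 FPKM, and Elane, neutrophil elastase, from 81.1 to 14.8 FPKM. Itgax, the integrin subunit CD11c of dendritic cells, rose from 10.6 to 75.3 FPKM. Vpreb1, a part of the surrogate light chain of B cell progenitors, rose from 8.32 to 81.3 FPKM. Elane was chosen after its values were seen. Of the 10066 expressed genes, 142 rose and 323 fell past 2-fold, 4.62% in all.

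The rises past the 2-fold rule in lineage B117 with the largest log2 ratios were in genes of many kinds. Glul, glutamine synthetase, went from 0.0328 to 15.6 FPKM. Nrgn, a calmodulin-binding protein best known in neurons, went from 2.77 to 40.8 FPKM. Tspan13, a tetraspanin, went from 14.9 to 107 FPKM, and Penk, the proenkephalin gene, from 1.46 to 14.9 FPKM. Zfp13, a zinc finger gene, was listed at 0 in B117P and at 7.15 FPKM in B117H. Lpcat2, Nrg4 and Rps27 rose with log2 ratios of 3.28, 3.18 and 3.09, but each overlaps another listed gene, and reads of Rps27 can be shared with a pseudogene.

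The falls with the largest log2 ratios in lineage B117 were led by Ly6c2, a surface marker of inflammatory monocytes, from 27.2 to 0.433 FPKM. Ccl4, an inflammatory chemokine, fell from 56.6 to 3.46 FPKM. Hpse, heparanase, fell from 9.60 to 0.115 FPKM, and Lmna, the A-type lamin gene, from 18.6 to 1.18 FPKM. Hpgd, which inactivates prostaglandins, fell from 13.8 to 0.857 FPKM. Xlr, Igsf6 and Mid1 fell with log2 ratios of -3.39, -3.36 and -3.31. Reads of Ly6c2 can be shared with its paralog Ly6c1, and Igsf6 overlaps Mettl9. Ddx3y, a Y-linked RNA helicase gene, fell with a log2 ratio of -3.02.

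Of the 17 expressed neutrophil and granulocyte genes, 8 fell in B117H, none rose and 9 did not pass the rule. Beside Ms4a3 and Elane, Csf3r, the receptor for granulocyte colony-stimulating factor, fell from 6.19 to 0.286 FPKM, and Mpo from 1450 to 473 FPKM. The list had a median log2 ratio of -0.99, below all random lists. Of 23 monocyte and macrophage genes, 9 fell, 1 rose and 13 did not pass. F13a1, a coagulation factor subunit made by monocytes, fell from 6.82 to 0.533 FPKM, Cd14, a co-receptor for lipopolysaccharide, from 37.8 to 11.5 FPKM, and Trem2, a lipid-sensing receptor of macrophages, from 3.90 to 0.203 FPKM. The median of this list was -0.73, also below all random lists.

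Inflammation, stress and glycolysis genes were also lower in B117H. Among 20 inflammation and NF-kB genes, 5 fell and none rose, with Ccl3, another chemokine, from 166 to 21.5 FPKM, Ptgs2, cyclooxygenase 2, from 4.68 to 0.522 FPKM and Osm, oncostatin M, from 2.94 to 0.575 FPKM. Among 24 immediate early and AP-1 genes, 3 fell, namely Ier3, Atf3 and Fos, with log2 ratios of -2.61, -2.37 and -1.07. Among 30 genes of the ATF4 amino acid response and the unfolded protein response, 3 fell: Atf3, Nupr1, a stress-induced chromatin protein, and Psph, an enzyme of serine synthesis, from 15.6 to 3.59 FPKM. Among 34 glycolysis and hypoxia genes, 4 fell and none rose. Hk3, the hexokinase of myeloid cells, fell from 116 to 32.9 FPKM and Pfkp, a phosphofructokinase, from 18.1 to 5.79 FPKM, although both overlap another gene. Ndrg1, a hypoxia-induced gene, fell from 45.1 to 19.7 FPKM. The median log2 ratios of these 4 lists were -0.50, -0.59, -0.34 and -0.49, each at percentile 0.01 or lower.

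Adhesion, histone and MHC class II genes also had lower medians in B117H, under fewer of the settings. Among 35 adhesion and migration genes, 6 fell and 1 rose, with a median of -0.24. Cd9, a tetraspanin, fell from 30.5 to 4.39 FPKM, and Itgb5, an integrin subunit, from 17.6 to 2.64 FPKM. Of 19 histone genes, 4 fell, among them Hist1h2bc, Hist1h3e and Hist1h1c on chromosome 13, and 11 of the 19 lay in regions of lower expression. The median of the histone list was -0.57. After the median of 25 neighbouring genes was subtracted, the adhesion and histone lists were at percentiles 6.24 and 55.1. Among 7 MHC class II genes, whose median was -0.81, Ifi30, a lysosomal thiol reductase, fell from 11.1 to 0.569 FPKM and H2-Ob rose. Without the filter that list was at percentile 2.87. With a minimum mean FPKM of 5 it was at 81.5 and the histone list at 51.3.

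Lipid synthesis, ribosomal protein, DNA repair, MHC class I and oxidative phosphorylation genes had higher medians in B117H. Among 31 sterol and fatty acid synthesis genes the median log2 ratio was 0.25, although 1 gene fell and none rose. Scd2, a fatty acid desaturase, fell from 720 to 187 FPKM, while Mvd, an enzyme of the mevalonate pathway, was at 37.7 and 70.8 FPKM. The 43 ribosomal protein genes had a median of 0.13, with 1 fall and no rise, and that fall, of Rpl30, overlaps another listed gene. The 41 DNA repair genes had a median of 0.16, with Xrcc5, the Ku80 subunit of DNA end joining, rising from 0.717 to 3.53 FPKM. The 20 MHC class I genes had a median of 0.13 and none passed the rule, and the 42 oxidative phosphorylation genes had one of 0.06 with 2 falls, of Ndufb8 and Uqcrfs1, and no rise. After the median of 25 neighbouring genes was subtracted, oxidative phosphorylation was at percentile 90.

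Stem and progenitor, T and NK, dendritic and stromal lists had higher medians in B117H, with few members past the rule. Among 15 stem and progenitor genes, with a median of 0.24, Angpt1, the angiopoietin ligand of the receptor Tie2, rose from 10.7 to 33.1 FPKM and none fell. Among 9 T and NK genes, with a median of 0.69, Klrd1, an NK receptor chain, rose from 3.33 to 10.4 FPKM, Cd6 and Lck rose, and Cd28, a T cell co-stimulatory receptor, fell from 39.0 to 9.19 FPKM. Among 8 dendritic cell genes, with a median of 0.40, only Itgax passed the rule. Among 4 stromal genes, with a median of 0.51, Pdgfrb, a growth factor receptor, rose from 1.55 to 7.54 FPKM and Fn1, fibronectin, from 1.85 to 5.69 FPKM. Without the filter on low values, which adds members that these lines barely express, the stem, T and NK, dendritic and stromal lists were at percentiles 52.6, 49.6, 88.2 and 48.8, and with a minimum mean FPKM of 5 the T and NK list was at 37.2. Of 14 B lymphoid genes 5 rose and 1 fell, with a median of 0.18 at percentile 97.4, just inside the central range of random lists, and at 100 with a pseudocount of 0.1.

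In B140H, the median of monocyte genes was higher than in B140P, and S100a10, Spint2 and Dntt were among the largest falls. S100a10, which binds annexin A2 at the membrane, fell from 106 to 0.401 FPKM, a log2 ratio of -6.25. Dntt, the terminal transferase of lymphoid progenitors, fell from 137 to 19.2 FPKM. Hp, the haemoglobin-binding protein haptoglobin, rose from 2.91 to 66.6 FPKM, and Mpeg1, a pore-forming protein of macrophages, from 12.3 to 76.7 FPKM. Of the 10066 expressed genes, 233 rose and 164 fell, 3.94% in all. The median log2 ratio of all expressed genes was 0.11 in this lineage and -0.03 in lineage B117, and after the libraries were centred, which moved the former by -0.13, the lineage B140 split became 158 higher and 200 lower.

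Other rises with large log2 ratios in lineage B140 were in Atp6ap1l, from 0.435 to 18.6 FPKM, and Hmgn3, a nucleosome-binding protein, from 3.50 to 36.5 FPKM. Mmp8, the collagenase of neutrophils, rose from 1.65 to 14.5 FPKM, and Myl4, a myosin light chain, from 91.6 to 518 FPKM. Rasa4, a GTPase-activating protein for Ras, rose from 4.19 to 28.3 FPKM, Col4a5, a basement membrane collagen, from 1.20 to 11.1 FPKM and Ttc39c from 0.201 to 7.02 FPKM. Among the falls, Spint2, an inhibitor of serine proteases, went from 27.2 to 0.173 FPKM, Serpinb8, another protease inhibitor, from 10.4 to 0.146 FPKM and Pde2a, a phosphodiesterase of cyclic nucleotides, from 9.94 to 0.270 FPKM. Ptpla fell from 16.1 to 1.29 FPKM. Cenpb, a centromere protein, and Pepd, a dipeptidase, were listed at 11.5 and 5.48 FPKM in B140P and at 0 in B140H, and an exact 0 can be a failed estimate. Hbb-b1 and Hbb-b2, the adult beta-globin genes, share 1 listed span and moved in opposite directions, and Amd1 shares its span with Amd2, so their ratios depend on how reads were divided between the pair.

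Of 23 monocyte and macrophage genes, 6 rose in B140H, 1 fell and 16 did not pass. The fall was of Ly6c2, from 2.35 to 0.0611 FPKM. Of the 23, 13 lay above the median log2 ratio of all expressed genes. F13a1 rose from 9.02 to 48.8 FPKM, Irf8, a transcription factor of monocyte and dendritic cell development, from 88.5 to 200 FPKM, Cd68, a lysosomal glycoprotein of macrophages, from 25.3 to 64.1 FPKM and Cx3cr1, the fractalkine receptor, from 5.67 to 15.2 FPKM. Cd68 and Cx3cr1 were chosen after their values were seen. The list had a median log2 ratio of 0.40, above all random lists, but without the filter on low values, which adds members that these lines barely express, it was at percentile 41.5. Of 17 neutrophil genes, 2 rose, 2 fell and 13 did not pass, with Mmp8 rising and Mpo falling from 10.4 to 0.913 FPKM. The median of the neutrophil list was -0.17 at percentile 0.32, but it was at 7.90 after the libraries were centred and at 44.3 without the filter.

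Proliferation, antioxidant and adhesion genes had higher medians in B140H. Of 39 cell cycle genes, with a median log2 ratio of 0.36, only Ccne1, cyclin E1, passed the rule, rising from 12.3 to 30.5 FPKM. Mcm7, a subunit of the replicative helicase, was at 139 and 253 FPKM. Of 23 NRF2 antioxidant genes, with a median of 0.41, Hmox1, haem oxygenase, rose from 3.81 to 17.9 FPKM, and Gpx1, a glutathione peroxidase, was at 620 and 1212 FPKM. Of 35 adhesion genes, with a median of 0.31, 4 rose and none fell. Spp1, the secreted matrix protein osteopontin, rose from 16.3 to 64.0 FPKM and Itgb7, an integrin subunit, from 17.9 to 41.9 FPKM, the latter chosen after its values were seen. Without the filter on low values the NRF2 and adhesion lists were at 83.7 and 95.2.

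Ribosomal, antigen presentation and growth factor receptor genes also stood apart in B140H. MHC class I genes had a median of 0.40, with 1 fall among 20, of Cd1d1, which presents lipids. MHC class II genes had one of -0.35, with none of 7 past the rule. After the median of 25 neighbouring genes was subtracted, these lists were at percentiles 78.4 and 26.2, and without the filter at 87.8 and 34.5. The 43 ribosomal protein genes had a median of 0.01, below all random lists, and the 37 ribosome biogenesis genes among Myc targets had one of 0.04 at percentile 0.11. Of those 37, Eif4e, the cap-binding translation factor, rose and Slc16a1, a lactate transporter, fell, the rise of Eif4e not passing the rule after centring. The 36 growth factor receptor and signalling genes had a median of -0.03 at percentile 1.57, with none past the rule, and were at 14.8 without the filter and at 2.91 with a minimum mean FPKM of 5, where the MHC class II list was at 71.1.

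**Figure D2:**
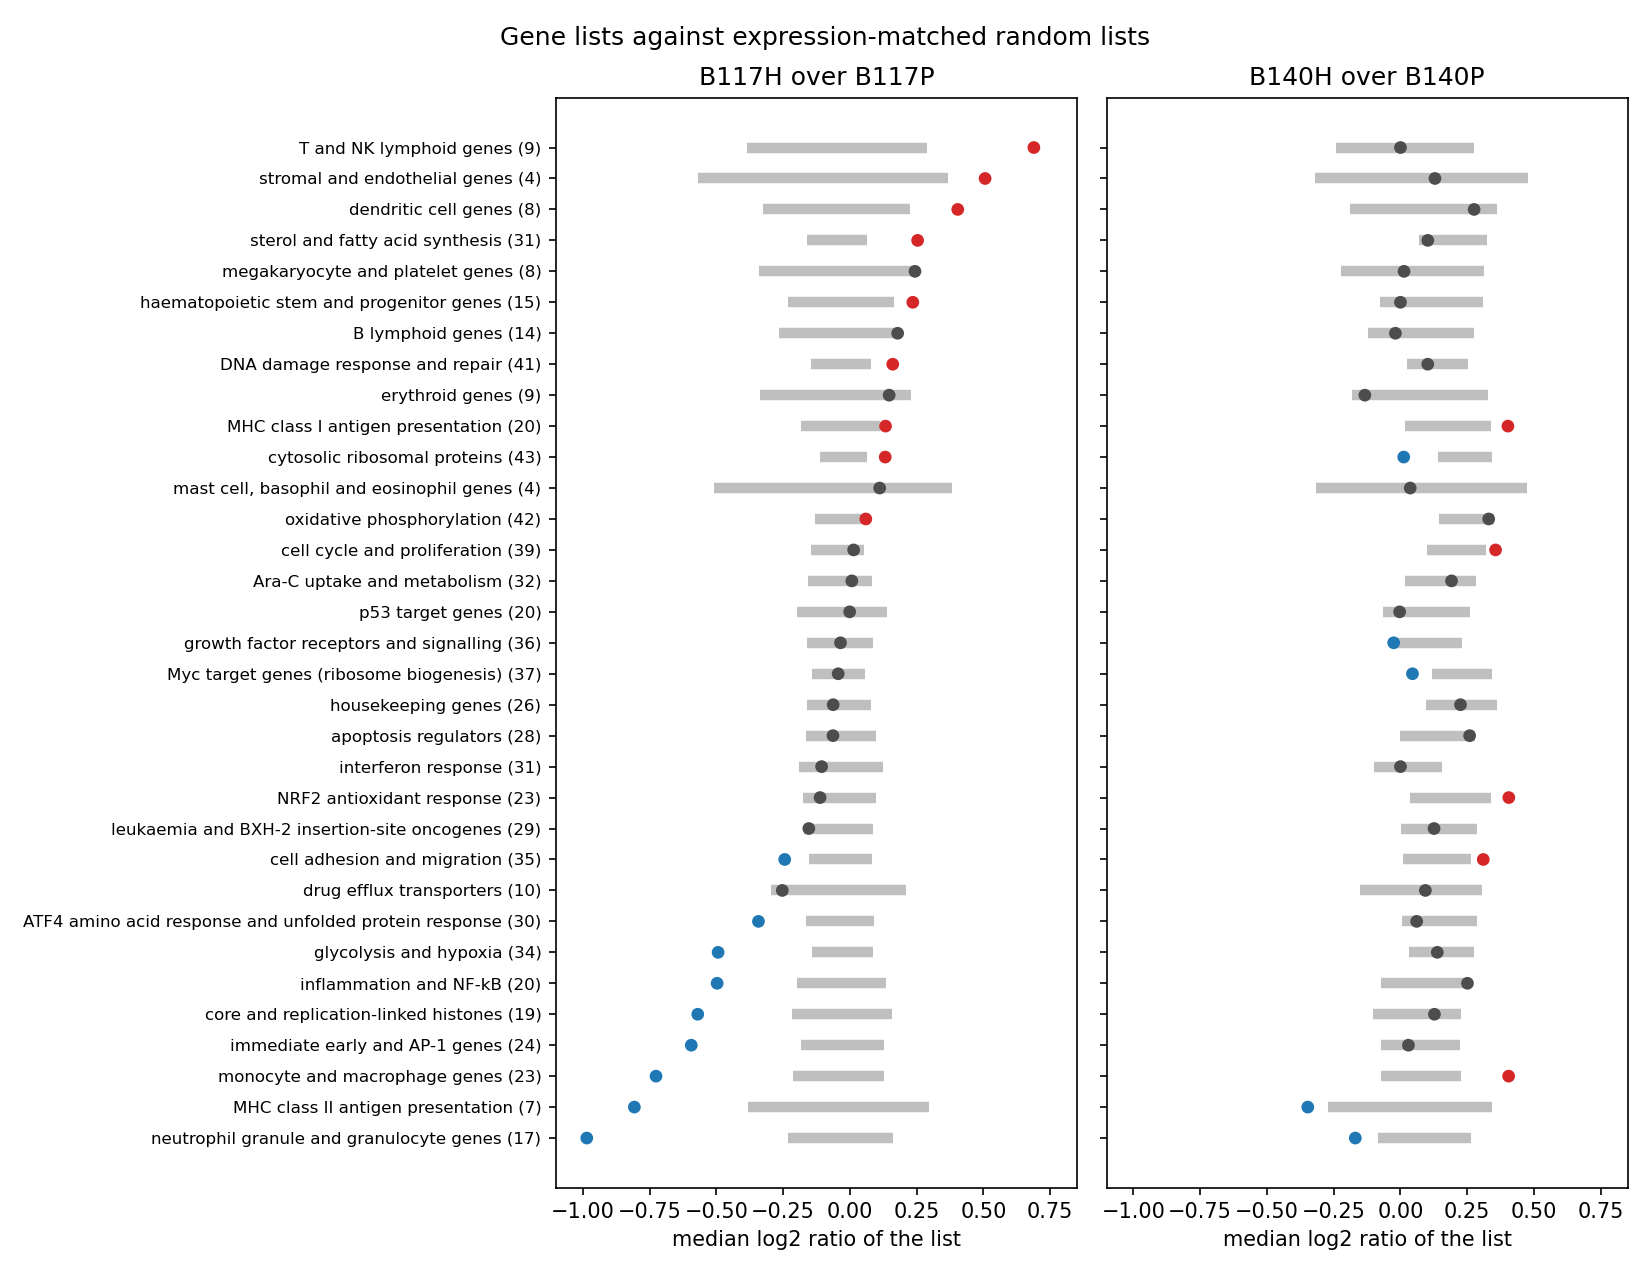
Median log2 ratio of FPKM + 1, resistant over parental line, of the expressed members of each gene list (points), with the central 95% of 10000 expression-matched random lists (grey bars), for lineage B117 and lineage B140. Red points stand apart as higher and blue as lower: 9 and 9 of 33 lists in lineage B117 and 5 and 5 in lineage B140.

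The next question is which genes changed the same way in both lineages. Dck, Ifitm1, Ly6c2, Mpo, Igfbp4, Dab2 and Ccbl2 fell in both resistant lines, and Fbxo44, Rtn4rl1, Pigk and Ankrd13c rose in both. Ifitm1 fell from 22.7 to 2.11 FPKM in lineage B117 and from 18.1 to 4.78 FPKM in lineage B140. Igfbp4, a binding protein of insulin-like growth factors, fell from 102 to 13.2 FPKM and from 105 to 45.8 FPKM. Dab2, an endocytic adaptor, fell from 68.7 to 12.3 FPKM and from 13.8 to 5.72 FPKM. Fbxo44, a substrate receptor of a ubiquitin ligase, rose from 2.34 to 7.26 FPKM and from 0.876 to 5.80 FPKM.

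In all, 12 genes rose in both lineages and 11 fell in both. Independent lists of those sizes would share 3.29 and 5.26 genes. That number treats every gene as equally likely to pass the rule, and the counts of opposite changes given below exceeded theirs too. An excess over it is therefore not by itself a sign of a shared or an opposed response. Without small RNA genes, whose FPKM values are unreliable at their length, 6 rose and 8 fell in both, where independent lists would share 2.57 and 4.43. Pigk, a subunit of the enzyme that attaches lipid anchors to proteins, had log2 ratios of 1.06 and 1.16, and Ankrd13c had a mean log2 ratio of 1.06 over the lineages. Rtn4rl1, a relative of the Nogo receptor, had 1.06 and 1.18. Ccbl2, which fell from 15.6 to 6.70 FPKM in lineage B117, was listed at 3.79 FPKM in B140P and at 0 in B140H.

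More genes changed in opposite directions than in the same one. Vpreb1 and Dntt, genes of lymphoid progenitors, rose in B117H and fell in B140H. Hp, Hpse, F13a1 and Spp1, which encode secreted proteins, fell in B117H and rose in B140H. Vpreb1 went from 8.32 to 81.3 FPKM in lineage B117 and from 54.8 to 14.1 FPKM in lineage B140. Dntt went from 44.2 to 222 FPKM and from 137 to 19.2 FPKM. The B lymphoid list that holds both did not stand apart in B140H. Of its 14 expressed genes 3 rose and 4 fell there, with a median log2 ratio of -0.02 at percentile 17.1.

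There were 10 genes up in lineage B117 and down in lineage B140, where independent lists would share 2.31, and 39 with the reverse pattern, where they would share 7.48. Of these 39, 13 were small RNA genes. Angpt1 went from 10.7 to 33.1 FPKM in lineage B117 and from 4.35 to 1.02 FPKM in lineage B140. Xrcc5 had log2 ratios of 1.40 and -2.02. Ppfibp1, whose span overlaps another gene, went from 0.765 to 3.98 FPKM and from 4.67 to 0.00830 FPKM. Spp1 went from 149 to 32.8 FPKM in lineage B117, and Hpse from 1.38 to 11.7 FPKM in lineage B140. Across all expressed genes the log2 ratios of the lineages had a Pearson correlation of -0.10 and a Spearman correlation of -0.14. Genes are not independent replicates, so no p is given, and whether a gene's change differed between the lineages was not tested.

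**Figure D3:**
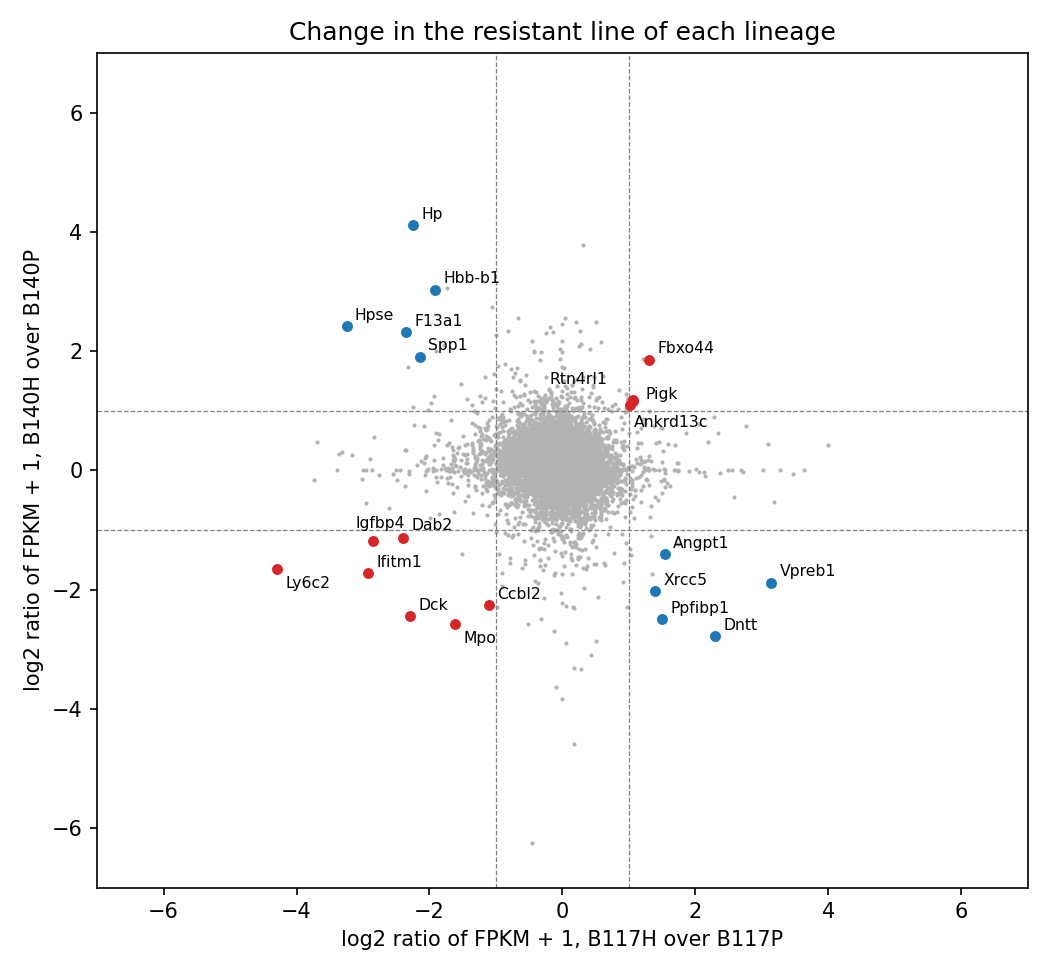
Log2 ratio of FPKM + 1 of each expressed gene other than small RNA genes in lineage B117 (horizontal) and lineage B140 (vertical), resistant over parental line, with dashed lines at the 2-fold rule. Named genes that changed the same way are red and those that changed in opposite directions are blue. Dck lies at -2.29 and -2.45.

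Median ratios were shifted along whole chromosomes and long regions, most of which differed between the lineages. In B117H the expressed genes of chromosome 12 were higher, with a median log2 ratio of 0.44 over 339 genes, and those of chromosomes 13 and 16 were lower, at -0.44 over 384 genes and -0.47 over 328 genes. In B140H the genes of chromosomes 9 and 14 were lower, at -0.20 over 539 genes and -0.24 over 346 genes, and those of chromosome 5 were higher, at 0.25 over 650 genes. Chromosomes 3 and 12 were lower there as well, at -0.03 over 467 genes and -0.04 over 339 genes, against 0.11 for all expressed genes. Chromosome 12 thus moved the other way from its rise in B117H. The medians of 7 of 20 chromosomes in lineage B117 and 6 of 20 in lineage B140 lay outside all random draws of as many genes.

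Windows of 25 neighbouring expressed genes placed these regions, with ends that are approximate because merged windows can run past a border. In lineage B117, 1015 of 9581 windows lay outside all random draws and merged into 11 regions. The higher ones included chromosome 12 from 3235791 to 119539913 and chromosome 3 from 137527563 to 159598139. The lower ones included chromosome 16 from 4594713 to 98303604, chromosome 13 from 3537321 to 62397849 and chromosome 15 from 3220767 to 38230462. The 66 expressed genes of that part of chromosome 15 had a median 1.18 below that of all genes (-1.18). The region of chromosome 5 from 77020739 to 106344837, which holds Dck, was also lower. In lineage B140, 885 windows merged into 12 regions. Chromosome 9 from 3335231 to 105034135, chromosome 14 from 37688122 to 123382483 and chromosome 3 from 90416816 to 132501470, which holds S100a10, were lower. Chromosome 3 from 127510183 to 159598139 and chromosome 5 from 130271434 to 145962751, which holds Rasa4, were higher. The lower and the higher region of chromosome 3 overlap between 127510183 and 132501470. The other 7 regions were each at most 2.36 Mb long, and with a minimum mean FPKM of 5 the lineage B140 windows gave 6 regions. The end of chromosome 3 was higher in both lineages, and with windows of 15 genes the end of chromosome 14 from 105513736 to 123382483 was lower in both.

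The regions were found from the same ratios, so the changed genes in them are counted only to place them. Lower regions held 8.68% of the expressed genes in lineage B117 and 170 of its 323 falls, 52.6%. Among the falls named above for B117H, Dab2 and Rpl30 lay in the lower region of chromosome 15. F13a1, Hk3, Pfkp and Uqcrfs1 lay in that of chromosome 13, and Itgb5 in that of chromosome 16. Scd2 and Ndufb8 lay in a lower region of chromosome 19, and Hpse and Spp1 in lower regions of chromosome 5. Ly6c2, Ccl4, Lmna and Mpo lay in no such region, and Vpreb1, which rose, lay in the lower region of chromosome 16. Lower regions in lineage B140 held 8.01% of the genes and 38 of its 164 falls, 23.2%. Higher regions held 4.57% of the genes and 29 of 142 rises in lineage B117, and 4.05% and 65 of 233 rises in lineage B140. After the median of 25 neighbouring genes was subtracted, 145 genes were higher and 175 lower in lineage B117, and Ms4a3 on chromosome 19 and Elane on chromosome 10 lay outside these regions.

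**Figure D4:**
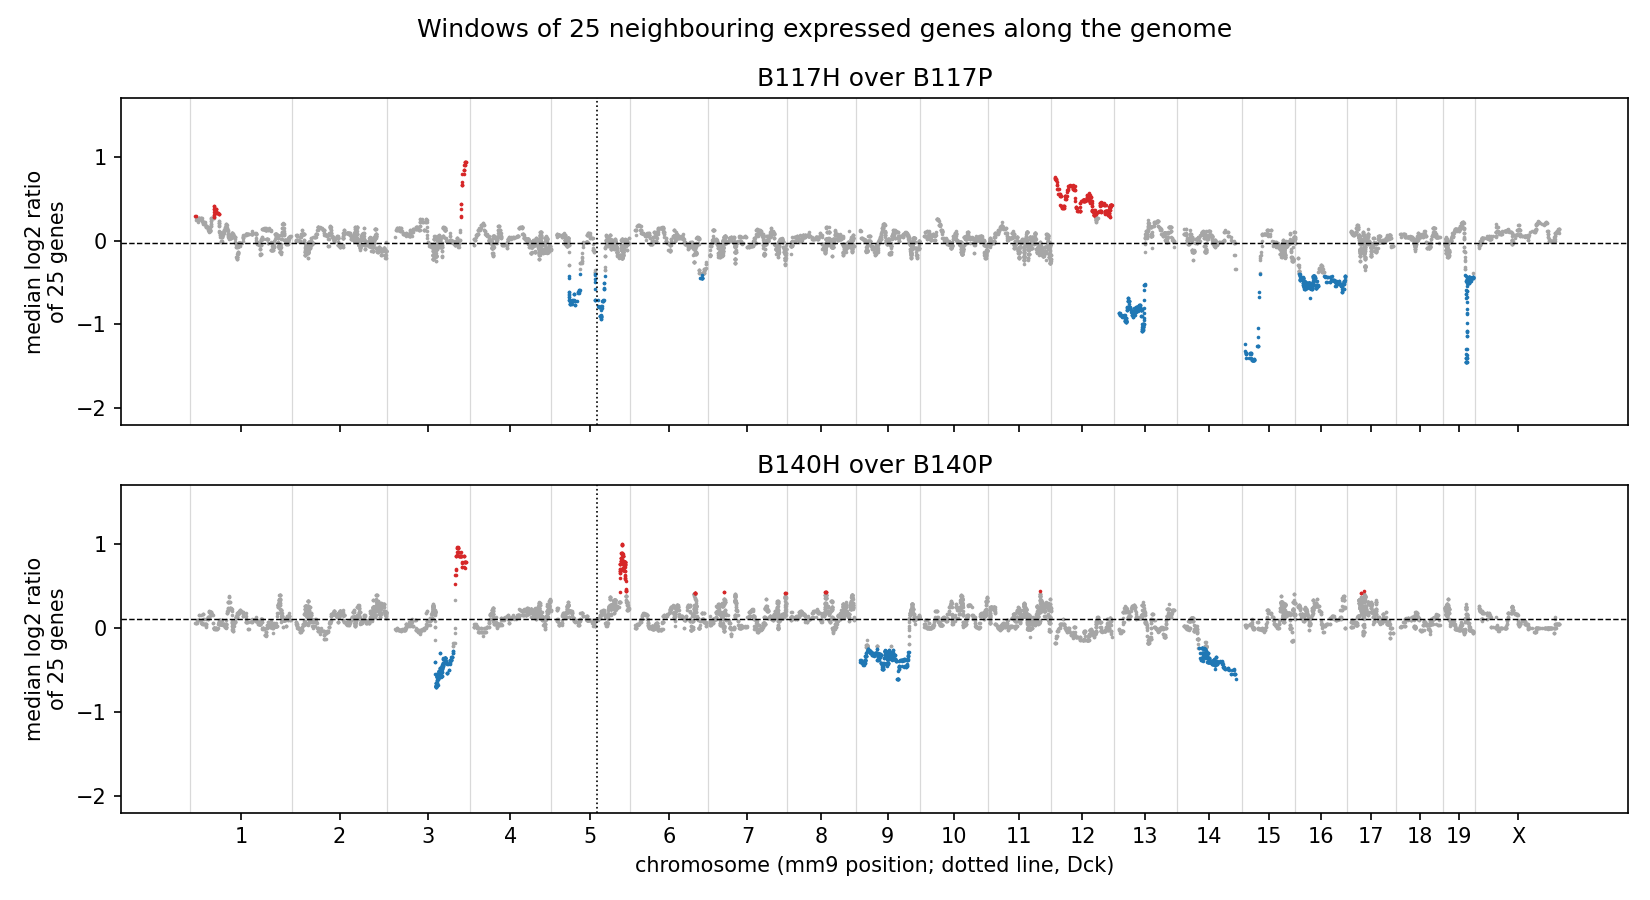
Median log2 ratio of windows of 25 neighbouring expressed genes along the chromosomes (mm9), for lineage B117 and lineage B140, with a dashed line at the median of all expressed genes. Windows outside all random draws, 1015 and 885 of 9581, are coloured, and the dotted line marks Dck.

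The parental lines differed from each other at more genes than either resistant line differed from its parent. B140P expressed B lymphoid and p53 target genes at higher levels than B117P, and neutrophil, monocyte and interferon response genes at lower levels. Cd34, a surface marker of progenitors, was at 200 FPKM in B117P and 0.0432 FPKM in B140P, and Kit, the stem cell factor receptor, at 29.9 FPKM and 0. Ebf1, a transcription factor of B cell commitment, was listed at 0 in B117P and at 24.7 FPKM in B140P. Meis1, a homeobox oncogene of myeloid leukaemia, was listed at 0 and at 14.4 FPKM. In all, 1674 of the 10066 expressed genes differed past 2-fold, 587 higher and 1087 lower in B140P. Cd34, Kit, Ebf1 and Meis1, and the genes named from here to the end of the account of the parental lines, were chosen after their values were seen.

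Of 14 B lymphoid genes, 12 were higher in B140P and none lower, with a median log2 ratio of 2.51. Igll1, the other part of the surrogate light chain, was at 0.118 and 38.0 FPKM, and Cd79b, a chain of the B cell receptor complex, at 1.67 and 44.5 FPKM. Of 20 p53 target genes, 8 were higher and none lower, with a median of 0.61. Cdkn1a, the cell cycle inhibitor p21, and Mdm2, the ubiquitin ligase of p53, had log2 ratios of 2.26 and 1.04, and Zmat3 was at 0.0625 and 18.1 FPKM. Both lists were above all random lists. Medians of ribosomal protein, ribosome biogenesis and oxidative phosphorylation genes were higher in B140P as well, at 0.30, 0.25 and 0.21.

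Of 17 neutrophil genes, 15 were lower in B140P, with a median log2 ratio of -2.55. Mpo was at 1450 FPKM in B117P and 10.4 FPKM in B140P, and Lyz2, lysozyme, at 68.7 and 0.765 FPKM. Of 23 monocyte genes 12 were lower and none higher, with a median of -1.04, and of 31 interferon response genes 17 were lower and none higher, with a median of -1.31. Ccr2, the receptor that draws monocytes to inflammation, was at 118 and 1.57 FPKM, and Gbp3, an interferon-induced GTPase, at 37.1 and 0.0201 FPKM. Of 30 genes of the ATF4 and unfolded protein responses 12 were lower and 1 higher, with Asns, asparagine synthetase, at 25.9 and 0.0562 FPKM. Of 35 adhesion genes 15 were lower and 3 higher, and of 20 inflammation genes 8 were lower and 1 higher. The medians of these 6 lists lay below all random lists, as did that of 31 sterol and fatty acid synthesis genes at -0.61.

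The remaining lists that were lower in B140P had medians of -0.53 for stem and progenitor genes, -0.99 for erythroid genes, -1.32 for T and NK genes and -1.42 for stromal genes. Growth factor receptor genes had one of -0.29, leukaemia and insertion-site genes -0.39, AP-1 genes -0.36 and histones -0.73. Evi2a, a gene at a common retroviral insertion site in BXH-2 leukaemias, was at 134 FPKM in B117P and 6.52 FPKM in B140P. Flt3, a receptor tyrosine kinase of progenitors and dendritic cells, was at 32.9 and 249 FPKM, against the direction of its list. These comparisons set the lineages side by side, so any separate normalisation by the authors enters them.

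The resistant lines differed from each other at 1900 genes, 975 higher and 925 lower in B140H. The differences in Cd34, Ebf1 and Meis1 between the parents, chosen after their values were seen, were present between the derivatives as well, while Vpreb1 and Dntt were higher in B140P than in B117P and lower in B140H than in B117H. Cd34 was at 206 FPKM in B117H and listed at 0 in B140H, Ebf1 was at 0.0230 and 23.7 FPKM, and Meis1 at 0.0303 and 18.8 FPKM. Ms4a3, at 15.3 FPKM in B117H, was listed at 0 in B140H. The median log2 ratio of all expressed genes between these libraries was 0.15, and after the libraries were centred 688 genes were higher and 1102 lower in B140H.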

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

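In this part, the subtraction of neighbouring genes was chosen after the data had been seen but before its own result was, and none of the differences between the lineages was tested, since each lineage has 1 library per line. The genes below passed the 2-fold rule one way in lineage B117 and the other way in lineage B140, the lists stood apart on opposite sides of random lists, and the values are the log2 ratio in lineage B140 minus that in lineage B117. Genes that rose in B117H and fell in B140H were Dntt at -5.08, Vpreb1 at -5.03, Ppfibp1 at -3.99, Xrcc5 at -3.43 and Angpt1 at -2.94. Genes that fell in B117H and rose in B140H were Hp at 6.36, Hpse at 5.67, Hbb-b1 at 4.95, F13a1 at 4.66 and Spp1 at 4.05. Hbb-b1 shares its span with Hbb-b2. The medians of monocyte and macrophage genes differed by 1.13, those of adhesion and migration genes by 0.55 and those of ribosomal protein genes by -0.12.

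Neutrophil and monocyte genes had lower medians in B117H, and monocyte genes had a higher median in B140H. Shifts of whole regions are argued against as the whole cause, since after the median of 25 neighbouring genes was subtracted the lists stayed at percentiles 0.0, 0.0 and 100. Among genes with a mean FPKM of 5 or more the percentiles were 0.0, 0.01 and 99.79. That mean runs over all 4 libraries, so members low in lineage B140 can pass through B117P. Members high in B117P are also favoured for a fall. This filter therefore cannot decide whether scatter of lowly expressed genes had a part. After the libraries were centred on the median ratio these lists still stood apart, but 1 factor per library moves the random lists as well. Centring is therefore a weak test of the authors' scaling. With a pseudocount of 0.1 the lists were at percentiles 0, 0 and 99.98. TPM, whose pseudocount equals 24.03 FPKM in B117P, put the neutrophil and monocyte lists of lineage B117 at 91.4 and 98.6. Without the filter the monocyte list of lineage B140 was at 41.5, so its shift rests on the expressed members. A change in the differentiation state of each line may underlie these shifts, as a hypothesis that 1 line per lineage cannot separate from drift in culture or from another mixture of cells.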

How the results depend on the processing

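Alternatives that left out small RNA genes, genes listed at 0 or the shift of neighbouring genes, and TPM without small RNA genes, were chosen after the data had been seen. Dck stayed past the 2-fold rule in the same direction in both lineages with a pseudocount of 0.1 and after centring. After TPM scaling its ratios were -1.81 and -1.79 relative to the shifts of 2.65 and -2.61 of all genes, but without that subtraction it was higher in B117H. Relative to those shifts, Nt5e and Nt5c3l in lineage B117 and Dguok in lineage B140 lost their call, at -0.78, 0.45 and 0.96. Of the 169 named genes in each lineage, 163 in lineage B117 and 158 in lineage B140 kept their side of the rule with a pseudocount of 0.1. After centring 168 in each did so, but relative to the shifts of 0.03 and -0.13 that centring gave to all genes. Subtracting those shifts undoes most of the centring, so that agreement was nearly fixed in advance. Over all expressed genes, without that subtraction, the rises in lineage B140 went from 233 to 158. Relative to the shifts of 2.65 and -2.61 after TPM scaling, only 96 in lineage B117 and 109 in lineage B140 kept their side. There 24 and 13 lost their call, 36 and 43 gained one, and 13 and 4 changed sign without passing the rule the other way. Genes listed at 0 in both lines of lineage B140, such as Penk and Xlr, gained theirs at 2.61, which is only the subtracted shift. With a pseudocount of 0.1, 707 genes changed in lineage B117, 647 in lineage B140, 64 the same way in both and 91 in opposite directions. With a minimum mean FPKM of 5, 308 and 260 changed, 1028 differed between the parental lines and 1225 between the resistant lines, 4 genes were called by limma and 6 regions were found in lineage B140; fewer genes enter there. A 4-fold rule gave 107 and 95 genes and 10 the same way. Leaving out small RNA genes gave 14 the same way, and leaving out genes listed at 0 gave 13. Windows of 15 genes gave 17 regions in lineage B117. Without the filter 3 lists stood apart in lineage B140. Centring changed the lineage B140 split to 158 higher and 200 lower, and TPM without small RNA genes to 175 and 268. Without the block, leaving out each library in turn gave from 0 to 10 limma calls. The adjusted p of Dck over the Ara-C list alone ranged from 0.000252 to 0.0224 over the alternatives with 4 libraries except the one without the filter, at 0.191, and from 0.0917 to 0.249 with a library left out, where the lone library of a group is assumed to vary like the others. Scaling to TPM over all genes gave 9350 and 9444 changed genes, 14 the same way, 8839 in opposite directions, 9534 between the parental lines, 6960 between the resistant lines and a correlation of -0.42. This scaling applies 1 factor per library and cannot reorder the genes of a library, so what it changed among genes comes from its pseudocount of 1, equal to 24.03 FPKM in B117P, 1.44 in B117H, 0.580 in B140P and 4.87 in B140H because small RNA genes set the totals. Relative to the shift of all genes, it reversed in this way the neutrophil list of lineage B140 (percentile 100) and the monocyte list of lineage B117 (98.6), while 8 lists of lineage B117 and 3 of lineage B140 no longer stood apart and 5 in each newly did. Under the other settings lists that newly stood apart were B lymphoid genes of lineage B117 with a pseudocount of 0.1 (percentile 100), with a minimum mean FPKM of 5 (99.98) and after subtraction of neighbours (99.97), interferon genes of that lineage without the filter (0) and after subtraction (1.37), and, after subtraction, leukaemia genes of that lineage (0.03) and apoptosis (99.23), erythroid (1.18) and AP-1 genes (2.10) of lineage B140. TPM scaling changed the sign, in lineage B117, of Zfp13 (-0.076), Fbxo44 (-0.19), Rtn4rl1 (-0.23), Pigk (-0.18), Ppfibp1 (-0.78), Xrcc5 (-0.91), F2r (-0.88), Cd6 (-0.49), Lck (-0.39), Pdgfrb (-0.10), Fn1 (-0.45), Gsta4 (-0.33) and Irf8 (0.13), and in lineage B140 of Ly6c2 (0.29), Cd1d1 (0.54), Xaf1 (0.49) and Elovl6 (0.24). Where no construction is named, the cause was not tested. A count-based test listed among the alternatives was not run, since read counts were not used here, and depth limits values below about 0.0785 FPKM on a 2 kb transcript.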

Other observations

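In this part, the tests of DNA copies, of a few strongly changed genes and of Dck were chosen after their results were seen, and so were the random draws of the shift left on chromosome 13 after regression, while the bound of 75% for GC content was set before its result and chromosome 13 was set apart afterwards. Apoptosis, drug efflux and leukaemia genes held single large changes in lists whose medians did not stand apart. In B140H, Bcl2, which blocks apoptosis, rose from 8.68 to 21.7 FPKM, and none of the 28 apoptosis genes passed the rule in B117H. The apoptosis list was at percentiles 29.0 and 95.2 in lineages B117 and B140. Abcb4, a phospholipid transporter, rose from 1.66 to 9.85 FPKM in B140H, and Abcc2, an organic anion pump, fell from 3.44 to 0.185 FPKM in B117H, in a list of 10 efflux transporters at percentiles 4.25 and 59.7. Of 29 leukaemia and insertion-site genes, at percentiles 4.80 and 35.6, Cebpb and Gfi1, transcription factors of myeloid differentiation, fell in B117H from 7.31 to 1.17 FPKM and from 4.56 to 1.28 FPKM. Irf8 fell in B117H and rose in B140H, while Sox4 fell from 23.9 to 11.1 FPKM in B140H. Of 20 p53 target genes, at percentiles 61.6 and 10.5, Cdkn1a fell from 23.6 to 10.1 FPKM in B117H and none passed the rule in B140H.

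Of 31 interferon response genes, at percentiles 14.4 and 39.7, 4 fell in B117H, among them Usp18 and Isg15, a pair of the ISG15 modification system, with log2 ratios of -1.74 and -1.66. In B140H 1 rose and Xaf1 fell. Of 9 erythroid genes, at percentiles 91.8 and 4.65, Gfi1b rose from 16.8 to 35.0 FPKM in B117H. Gfi1b is a transcriptional repressor that acts in red cell and platelet development. Rhd, a blood group antigen, rose from 1.57 to 4.98 FPKM in B140H. Of 8 megakaryocyte genes, at percentiles 97.2 and 42.6, F2r, a thrombin receptor, rose and Cd9 fell in B117H, and of 4 mast cell and basophil genes, at 76.4 and 42.4, Mcpt8, a basophil protease, fell from 15.5 to 5.65 FPKM in B140H. None of 26 housekeeping genes passed the rule in either lineage, at percentiles 27.7 and 47.2. The Y-linked genes Ddx3y and Uty were at 7.47 and 1.99 FPKM in B117P, and at 0.0432 FPKM and 0 in B117H. B117H kept 0.579% of the parental Ddx3y level, with a counting interval of 0.16% to 1.52%, and B140H kept 89.7% of Ddx3y and 79.0% of Uty. The end of chromosome 3 from 137527563 to 159598139 was, with windows of 25 genes, the one region found in both lineages, with 46 expressed genes and median log2 ratios of 0.65 and 0.83. It holds Pigk and Ankrd13c, which rose in both, and Ccbl2, which fell in both.

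Median ratios were shifted along whole chromosomes and long regions. GC content, transcript length and expression level are argued against for chromosomes 12, 16, 9 and 14, which kept at least 90.51% of their shift after regression on them, and as the whole cause for chromosome 13, which kept 74.75%, just under the bound of 75%, but whose remaining shift of -0.30 lay below all random draws. The smallest shares of genes on the side of the shift were 89.33% for chromosomes 12 and 16, 83.24% for chromosome 14 and 64.84% for chromosomes 13 and 9. The lower end of the 95% interval was at 59.8% or higher. A first bound of 80% was replaced by these intervals after the shares were seen. These chromosomes were picked for a shifted median, which already places more than 50% of their genes on that side. The shares therefore describe how widely each shift was spread and cannot decide whether a few strongly changed genes were the cause. A gain or loss of DNA copies stays open, since the 100% of windows of chromosomes 12 and 16 on the side of the shift restate it. DNA was not measured, and whether the shifts came with resistance or with time in culture was not tested.

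Dck was lower in both resistant lines. Lower expression of the whole region is argued against as the whole cause, because the median log2 ratio of its 20 neighbours lay above that of Dck by 1.75 in lineage B117 and by 2.49 in lineage B140. At the estimated depth, counting error is argued against, since the upper ends of the intervals of the share left reached at most 19.1%. A change at the Dck locus itself, or in its regulation, may account for the remainder, but neither was tested, since no sequence was analysed here. In lineage B117 the lower region around Dck may add to the fall, as the difference of 1.75 is smaller there.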
